A study of Homo sapiens with 48 samples.

How the data were processed

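Total RNA of MCF7 cells was made into directional paired-end libraries with a NEBNext Ultra II kit, per the labels, from cells held at stepwise rising doses of doxorubicin or epirubicin or in DMSO. The 48 libraries fall into 16 groups of 3, and the labels number the libraries of a group as biological replicates. The submitters' processing notes name Trimmomatic 0.38, STAR 2.7.3a, Subread 2.0.0, edgeR 3.34.1 and the GRCh38.p13 genome, with no role or order. The annotation, the strand setting of the counting and the gene filter are not given in the sources used here, so reads of genes that overlap on opposite strands cannot be told apart with certainty.

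The authors deposited 2 tables, 1 per drug, each with 24 libraries, and the values per library are log2 CPM per the file headers. The authors' deposited tables also hold log2 fold changes of each dose against that drug's control and FDR-adjusted p-values, of which only the counts of genes past 0.05 are given here, named as the authors'. They hold 13917 genes for doxorubicin and 13934 for epirubicin, and 0 columns of values per library were left unmapped. The tables were normalized separately, so tests were run within a table, and the drugs were compared only by the difference of changes taken within each table.

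The values were worked back to reads. At values up to 10000 reads, 100% came out whole within a tolerance of 0.1 reads in every library, with a mean prior of 0.125 reads, which gave the depth of each library, 25.25 to 59.39 M reads, and scaling factors from 0.9276 to 1.0475. Fold changes are on this log2 scale with the authors' prior count, which understates the change of genes with few reads. Between 20 and 239 genes per library were at 0 reads, and the 10 highest genes took 5.98% to 10.1% of the reads. Replicates were compared by a chi-square of their reads over genes, which was 5.49 to 88.74 per degree of freedom over 48 pairs, and the controls of the tables by the same measure, which was 35.57 to 74.46 over 9 pairs, so no library was counted as a copy of another. Intervals given for changes come from the fitted model and hold for these libraries.

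Gene positions came from GENCODE release 29 on GRCh38, in which 13914 of 13917 and 13931 of 13934 gene IDs matched, 99.9% of them protein coding. Genes with log2 CPM over 0 in at least 3 libraries of a table were tested, 12862 for doxorubicin and 12840 for epirubicin, with 12659 tested in both.

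Each dose was compared with its own control by limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with trend, two-sided) on all 24 libraries of that drug as 8 groups, with Benjamini-Hochberg adjustment within each contrast and a threshold of 0.05. The difference between drugs at a dose was tested in 1 fit of 48 libraries as 16 groups. Adjusted p-values are from these fits unless named otherwise. Version 1.17.8 of data.table and version 1.5.0 of statmod were also used, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 for reading and plotting. Choices of test, filter, gene lists, named genes and alternatives were made before the data were examined, except where another time is given.

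Gene lists numbered 30, and 29 had measured members. They were anthracycline targets and metabolism, ABC transporters, p53 targets, proliferation, histones, recombination and Fanconi repair, end joining and mismatch repair, BCL2 family, estrogen response, luminal identity, basal epithelium, epithelial junctions, mesenchymal genes, leukocyte markers, ovarian carcinoma markers, interferon response, antigen presentation, NF-kB and secreted factors, folate and one-carbon metabolism, amino acid carriers, ATF4 and unfolded protein response, NRF2 targets, lysosome, cholesterol synthesis, glycolysis, nuclear respiratory chain, mitochondrial genome, ribosomal proteins and stem-like markers. Of the list of nuclear-retained and short structural RNAs, 0 of 20 members were measured. Lists were tested with limma's camera with a preset correlation of 0.01 at 100 nM, adjusted over the lists of a contrast, and the same test at the other doses was added after the data were examined. Camera with an estimated correlation and limma's fry were alternatives, and of fry the directional test asks whether a list's genes move one way on balance and the mixed test whether they change in either direction.

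Genes were named by a rule. At 100 nM of each drug the 8 highest and 8 lowest log2 fold changes were taken among genes past the threshold with a mean log2 CPM of at least 2 and all 3 treated libraries outside the control range, with no clone or pseudogene names. At each other dose 2 and 2 were taken, for the difference 6 and 6 at 100 nM and 1 and 1 elsewhere, and per list up to 4 members by adjusted p for each drug and 2 for the difference. Always included were SLC38A7, SLC46A1, ABCB1, ABCC1, ABCG2, TOP2A, TOP2B, CDKN1A, MDM2, ESR1 and MKI67, and UGT2B7 and SLC22A16, which are not in the tables analysed here. Genes of the parts at other doses and of the lists were left out of the text for length, without regard to direction. SARM1 and the neighbours of ABCB1 were chosen after the data were examined.

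Overlaps of calls between drugs were set beside the overlap of independent lists, the product of both counts over the genes tested, and persistence to 100 nM also beside simulated unchanged groups against the same controls. Replicate numbers are shared between groups in the labels. At doxorubicin 100 nM same-numbered libraries deviated together from their group means as the controls did, with correlations across genes of 0.31 to 0.55 in 3 of 3 pairs. Each library correlated best with its own number. Deviations cancel out within a group, so these pairs are not independent, and this is a hint from the data and not from the labels. With the replicate as a block, 8957 genes passed at doxorubicin 100 nM, against 8934 without it. In the other contrasts not every pair was over 0.1. Under epirubicin some control libraries deviated together with treated libraries of another number. The highest such correlations were 0.56 and 0.63 at 5 nM, 0.57 at 25 nM and 0.4 at 1 nM. At 5 nM the same-numbered pairs of those controls were at -0.65 and -0.54. A block on the replicate number does not take up such pairs.

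Alternatives tried were no filter, a stricter filter (log2 CPM over 2), 1 CPM added, only the compared groups fitted, the replicate block, eBayes without trend, scaling to library medians, quantile normalization, each library left out in turn, 2-fold calls for overlap and persistence, and, added after the data were examined, limma's voom on the recovered reads.

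The procedure was tested on simulated data with 200 changed genes, 50 per fold size. The real contrast at doxorubicin 100 nM had 8934 calls, and the adjustment is looser where more genes change, so recovery there may differ. For simulated doxorubicin 100 nM the procedure recovered 52%, 88%, 92% and 100% of genes changed 1.25-, 1.5-, 2- and 4-fold, with 9 false calls over 12862 genes. For epirubicin 100 nM the shares were 34%, 82%, 92% and 94%, with 6 false calls over 12840 genes, and for the difference at 100 nM 22%, 74%, 86% and 96%, with 10 false calls over 12659 genes. In a simulated list test on 12862 genes the 1 list raised 1.5-fold was called and 0 of the others. Whether this result and the false calls above hold where genes vary together was not shown. At epirubicin 100 nM the estimated correlation within measured lists was 0.88 for the mitochondrial genome and 0.85 for ribosomal proteins. Of the 11 list calls at 100 nM, 0 passed with an estimated correlation.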

Results

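RNA was sequenced from MCF7 cells, an estrogen receptor positive luminal breast adenocarcinoma line with wild-type TP53, as the cells were taken stepwise through rising doses of doxorubicin or epirubicin. Both drugs are anthracyclines, DNA-intercalating poisons of topoisomerase II, and they are stereoisomers that differ in the orientation of a hydroxyl group on the sugar. Each drug had its own DMSO control and 7 doses, of which the lowest was 1 nM and the others were 5, 10, 15, 25, then 50 and at last 100 nM. Each of the 16 groups held 3 libraries described as biological replicates, 48 in all. The sources used here do not say whether the replicates of a dose were selected separately, so the p-values measure the spread between these libraries. Since the doses were taken in steps, an effect of dose cannot be told apart from time in culture. A difference between the drugs likewise cannot be told apart from separate histories of the cultures. The recovered depth was 25.46 to 59.39 M reads per library in the doxorubicin table and 25.25 to 52.4 M in the epirubicin table. No pair of replicates agreed within sampling noise, since the chi-square per degree of freedom ran from 5.49 to 88.74 over 48 pairs. Levels are given as CPM, reads scaled to library size, with mean ± SD and n = 3, and changes as log2 fold changes on the authors' log2 CPM scale with the standard error (SE). The study's title names dependencies on SLC38A7 and SLC46A1 in the evolution of resistance, and the design asks what changed from the control at each dose and where the drugs differed at matched doses.

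The number of genes past the threshold was higher at each dose step up to 15 nM under both drugs. Genes changed at least 2-fold were fewer at 5 than at 1 nM, 185 against 263 under doxorubicin and 653 against 770 under epirubicin. Under doxorubicin, 1337 genes rose and 1324 fell at 1 nM, 1581 and 1516 at 5 nM, 2862 and 2831 at 10 nM, and 4664 and 4769 at 15 nM (limma, adjusted p under 0.05 within each dose, 12862 genes tested). At 25, 50 and 100 nM of doxorubicin 4540, 4572 and 4571 genes rose and 4543, 4445 and 4363 fell. Under epirubicin, 3026 genes rose and 2921 fell at 1 nM, 3159 and 3243 at 5 nM, 4598 and 4508 at 10 nM, and 4741 and 4557 at 15 nM, of 12840 tested. At 25, 50 and 100 nM of epirubicin 4213, 4323 and 4462 genes rose and 4077, 4158 and 4301 fell. Most changes were small: the median absolute log2 fold change at 100 nM was 0.346 under doxorubicin and 0.379 under epirubicin, and at least 2-fold changes numbered 837 up and 792 down, and 849 up and 767 down. These 2-fold counts depend on the prior count, since with 1 CPM added the totals at 100 nM were 985 against 1629 and 1011 against 1616. The authors' deposited table had 9173 genes past the same threshold at doxorubicin 100 nM and 9129 at epirubicin 100 nM, among all genes deposited. Of these, 8810 and 8745 were tested here, and 8761 and 8667 were also called here in the same direction. The counts at low doses leaned on single libraries. At doxorubicin 1 nM 1665 genes passed without 1 nM replicate 1. At doxorubicin 5 nM 1800 passed without 5 nM replicate 3 and 1830 without control replicate 2. With all libraries kept, other settings gave 2246 to 2777 genes at doxorubicin 1 nM and 2206 to 3233 at 5 nM. For epirubicin they gave 5216 to 6042 and 4903 to 6509. The ranges overlap, so a growth from 1 to 5 nM is not settled. Nor is one from 10 to 15 nM epirubicin, where they gave 8348 to 9432 and 8482 to 9688.

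**Figure D1:**
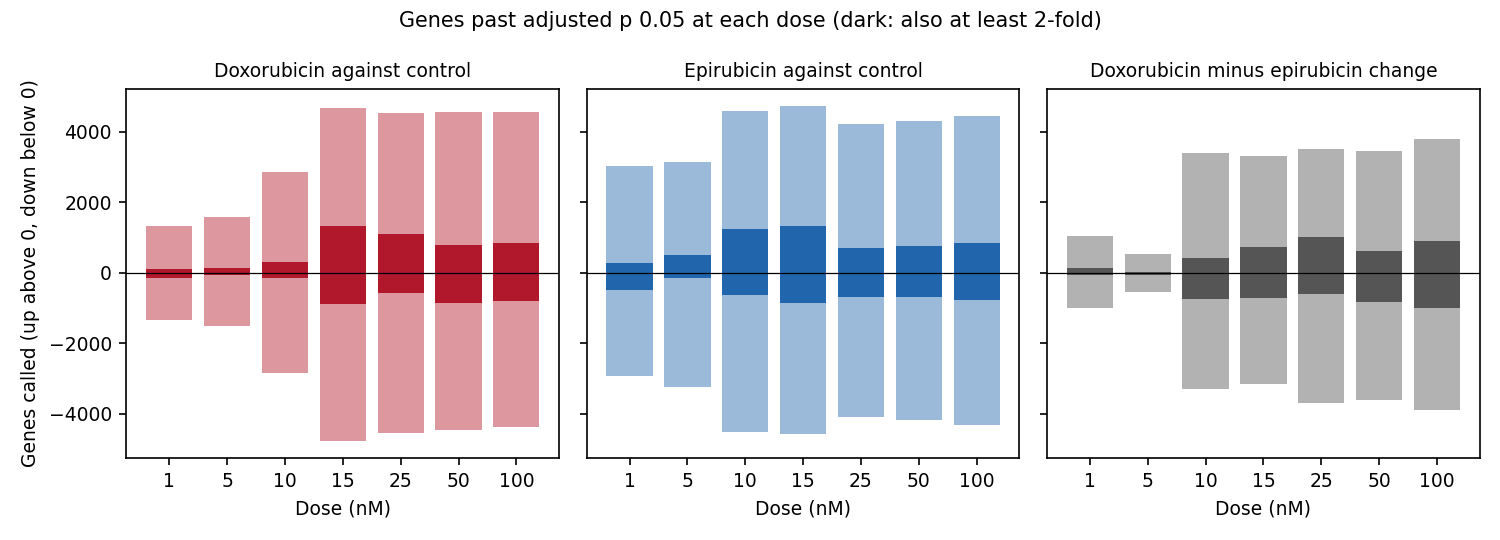
Number of genes higher (above 0) and lower (below 0) than the control at each dose in nM, for doxorubicin and epirubicin, with the genes changed at least 2-fold drawn within the bars. At 1 nM 1337 and 3026 genes were higher under doxorubicin and epirubicin, against 4664 and 4741 at 15 nM.

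SLC38A7, a lysosomal amino acid transporter that exports glutamine (ENSG00000103042, chromosome 16, 58665109 to 58685104, GRCh38), rose under both drugs and stayed high. Under doxorubicin its log2 fold change was 0.32 at 5 nM, 0.75 at 10 nM, 1.71 at 15 nM, 1.21 at 25 nM, 1.10 at 50 nM and 1.14 ± 0.08 (SE) at 100 nM (limma adjusted p = 3.8e-11). Its level went from 9.18 ± 0.808 CPM (SD, n = 3) in the control to 30.0 ± 1.78 at 15 nM and 20.2 ± 0.212 at 100 nM. Under epirubicin the log2 fold change was 0.44 at 5 nM, 1.42 at 10 nM, 1.49 at 15 nM, 1.31 at 25 nM, 1.21 at 50 nM and 1.26 ± 0.08 at 100 nM (adjusted p = 1.8e-11). Its level there went from 10.6 ± 0.32 to 25.6 ± 2.37 CPM. At 1 nM SLC38A7 was at 0.13 under doxorubicin (adjusted p = 0.291) and fell by 0.23 under epirubicin (adjusted p = 0.0252). The change in SLC38A7 differed between the drugs at 10 nM, by -0.67 (95% interval -0.90 to -0.44, adjusted p = 5.48e-06), being larger under epirubicin, and at 1 nM by 0.36 (adjusted p = 0.0274). At 100 nM the difference was -0.12 (-0.35 to 0.11, adjusted p = 0.35). The call at doxorubicin 5 nM was lost when only those groups were fitted (adjusted p = 0.051), as were those of epirubicin 1 nM and of the 1 nM difference. The epirubicin 1 nM call was also lost with voom or without epirubicin control replicate 2 or 3 or 1 nM replicate 1 or 3 (adjusted p from 0.0542 to 0.0841). The 1 nM difference was lost as well with voom or without doxorubicin control replicate 2 or 3, doxorubicin 1 nM replicate 2, epirubicin control replicate 3 or epirubicin 1 nM replicate 1 or 3 (0.0506 to 0.0832). At 15 nM a difference in SLC38A7 of 0.22 (adjusted p = 0.103) passed without doxorubicin control replicate 1 (0.0457) or epirubicin 15 nM replicate 1 (0.0416).

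SLC46A1, the proton-coupled folate transporter (ENSG00000076351, chromosome 17, 28394756 to 28407197), rose under both drugs, and more under epirubicin at 1 nM and from 10 nM. Under doxorubicin the log2 fold change was 0.23 at 1 nM, 0.30 at 5 nM, 0.49 at 10 nM, 0.70 at 15 nM, 0.68 at 25 nM, 0.51 at 50 nM and 0.50 ± 0.08 (SE) at 100 nM (limma adjusted p = 6.33e-06). Its level went from 18.3 ± 0.366 to 25.9 ± 2.19 CPM (SD, n = 3). Under epirubicin it was 0.60, 0.45, 0.96, 0.99, 1.18, 1.33 and 1.33 ± 0.08 at the same doses (adjusted p at 100 nM = 1.14e-11), from 14.2 ± 0.113 to 35.8 ± 0.113 CPM. The difference between the drugs in SLC46A1 was -0.37 at 1 nM (adjusted p = 0.0242), -0.46 at 10 nM, -0.28 at 15 nM, -0.51 at 25 nM, -0.82 at 50 nM and -0.84 at 100 nM (95% interval -1.07 to -0.60, adjusted p = 9.04e-08). At 5 nM it was -0.15 (-0.39 to 0.08, adjusted p = 0.445). Part of the SLC46A1 body is overlapped on the other strand by SARM1, whose log2 fold change at 100 nM was -0.30 under doxorubicin and -0.06 under epirubicin. The strand setting of the counting is not given in the sources used here. The doxorubicin call at 1 nM (adjusted p = 0.0414) was lost without any control, without 1 nM replicate 1 or 3 and with voom or quantile normalization (0.0654 to 0.127). The 1 nM difference was lost without doxorubicin control replicate 1, doxorubicin 1 nM replicate 2, epirubicin control replicate 3 or epirubicin 1 nM replicate 1 or 3 (0.0503 to 0.0724). The 15 nM difference (adjusted p = 0.0386) was -0.18 without doxorubicin 15 nM replicate 1 (0.194). It also missed the threshold with voom, without doxorubicin control replicate 1 or 3, without any epirubicin control and without epirubicin 15 nM replicate 2 or 3 (0.05 to 0.0741).

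**Figure D2:**
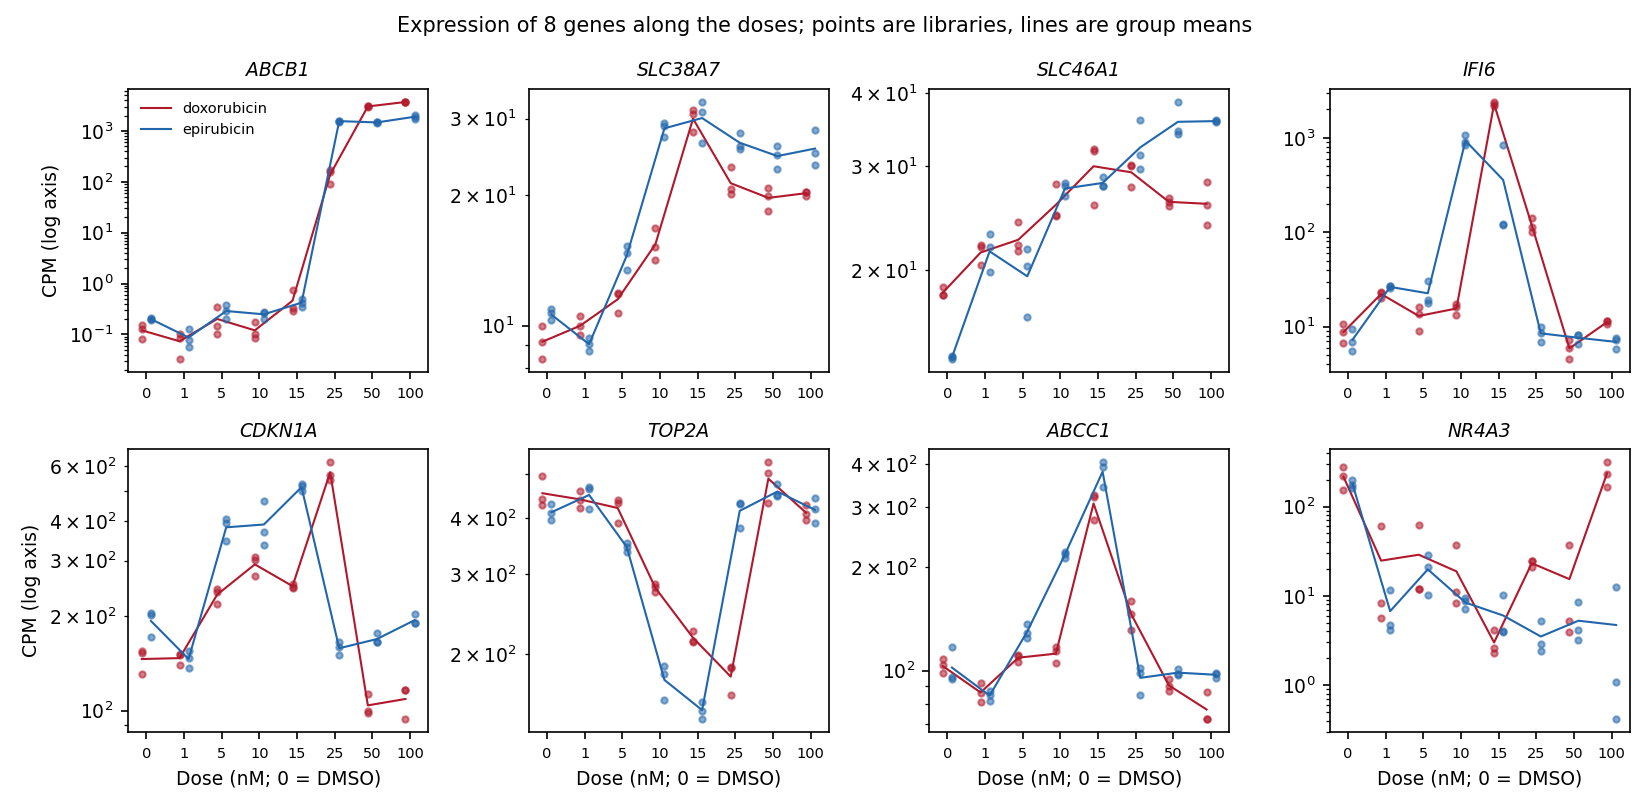
CPM on a log axis against dose in nM for 8 genes, with points for libraries and lines through group means, doxorubicin and epirubicin apart. ABCB1 stays under 1 CPM up to 15 nM and reaches 139 ± 43.0 CPM under doxorubicin and 1560 ± 65.8 under epirubicin at 25 nM.

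At each low dose of doxorubicin, 1 to 10 nM, the lowest log2 fold changes among genes that met the naming rule were those of NR4A3, an orphan nuclear receptor of the immediate early genes, and CYP1A1, a xenobiotic-metabolizing enzyme induced through the aryl hydrocarbon receptor. NR4A3 fell by 3.90 at 1 nM (217 ± 63.7 to 24.8 ± 31.0 CPM, limma adjusted p = 0.00135), fell by 3.35 at 5 nM and fell by 3.8 at 10 nM. CYP1A1 was at -5.17, -4.47 and -3.6 at these doses. At 1 nM IGFBP6, a secreted binder of insulin-like growth factors, rose by 2.52 ± 0.13 (SE; 6.75 ± 0.10 to 38.8 ± 0.396 CPM) and the stress kinase NUAK2 by 1.78. At 5 nM MUC16, the mucin that carries the CA-125 antigen, rose by 2.13 and PPP1R3C, a glycogen-targeting phosphatase subunit, by 1.84. At 10 nM GPNMB, a lysosomal glycoprotein, rose by 2.68 and DHRS2, a short-chain dehydrogenase, by 2.51. Targets of p53 rose as a group at 5 nM, with 21 of 35 up and 2 down (23 and 2 adjusted over the list alone; camera adjusted p = 6e-09, adjusted p = 0.214 with an estimated correlation). Among them CDKN1A, the p21 cell cycle inhibitor, rose by 0.68 ± 0.08. Proliferation genes fell at 5 nM, 20 of 45 with 0 up (21 adjusted over the list alone; adjusted p = 2.01e-07, adjusted p = 0.626 with an estimated correlation). Interferon-stimulated genes, which act against viruses, rose at 1 nM with 20 of 41 up and 1 down (25 and 1 adjusted over the list alone; adjusted p = 6.16e-09, adjusted p = 0.45 with an estimated correlation). Replication-dependent histones rose at 10 nM, 13 of 19 with 0 down (15 adjusted over the list alone; adjusted p = 3.3e-05, adjusted p = 0.693 with an estimated correlation), though their near-identical copies make single members uncertain. NR4A3 and CYP1A1 varied widely between libraries, with CYP1A1 at 45.2 ± 34.8 CPM in the doxorubicin control. List tests at doses below 100 nM were added after the data were examined, which makes 609 list tests in all, and 148 of these passed within their dose, 4 of them also with an estimated correlation.

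At 15 nM doxorubicin every measured member of the interferon list rose, 41 of 41 with a median log2 fold change of 5.41 (41 adjusted over the list alone; limma's camera adjusted p = 2.32e-20, and adjusted p = 0.0197 with an estimated correlation). IFI6, an interferon-induced mitochondrial protein, rose by 8.05 ± 0.19 (SE) from 8.77 ± 2.07 to 2280 ± 117 CPM (adjusted p = 7.98e-20). UBE2L6, which conjugates ISG15, rose by 7.01 ± 0.25 from 1.39 ± 0.161 to 179 ± 5.49 CPM. Antigen presentation genes rose with them, 20 of 20 with a median of 3.96 (20 adjusted over the list alone; adjusted p = 2.81e-10, and adjusted p = 0.0197 with an estimated correlation). HLA genes share near-identical sequence and are uncertain singly. DIO2, an iodothyronine deiodinase, fell from 19.8 ± 6.23 to 0.0462 ± 0.0162 CPM and the lectin REG4 from 8.17 ± 0.164 to 0.0767 ± 0.0535. The NF-kB and secreted factor list had 12 of 19 up and 2 down (same counts adjusted over the list alone; adjusted p = 0.00658, adjusted p = 0.105 with an estimated correlation). At 25 nM the interferon list still had 35 of 41 up and 2 down, with a lower median of 2.29 (same counts adjusted over the list alone; adjusted p = 1.03e-08, adjusted p = 0.215 with an estimated correlation). At 50 nM it had 12 up and 14 down (same counts adjusted over the list alone) with a median of 0.00. At 100 nM it had 12 up and 11 down (10 and 11 adjusted over the list alone; adjusted p = 0.963) with a median of 0.00.

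At 25 nM doxorubicin the p53 targets reached their highest median, 0.69, with 27 of 35 up and 3 down (same counts adjusted over the list alone; limma's camera adjusted p = 3.42e-06, adjusted p = 0.215 with an estimated correlation). CDKN1A rose by 1.97 ± 0.08 (SE), from 146 ± 13.2 to 573 ± 39.3 CPM, and MDM2, the ubiquitin ligase of p53, by 0.69 ± 0.05. Of 45 proliferation genes 41 fell and 1 rose, with a median of -0.65 (42 and 1 adjusted over the list alone; adjusted p = 4.54e-12, adjusted p = 0.281 with an estimated correlation). TOP2A, the topoisomerase II isoform of cycling cells and a target of these drugs, fell by 1.35 to reach 178 ± 14.3 CPM from 454 ± 35.9, and TOP2B, the other isoform, fell by 0.85. All 43 cytosolic ribosomal protein genes measured fell, with a median of -0.47 (43 adjusted over the list alone; adjusted p = 1.28e-12, adjusted p = 0.281 with an estimated correlation). Of 35 lysosomal genes 25 rose and 2 fell (same counts adjusted over the list alone; adjusted p = 6.89e-05, adjusted p = 0.281 with an estimated correlation). GPNMB rose by 5.30 to 37.8 ± 1.76 CPM, and CCN5, a secreted matricellular protein, and BRINP3 were at -6.66 and -5.77.

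ABCB1, the drug efflux pump P-glycoprotein (ENSG00000085563, chromosome 7, 87503633 to 87713323), was near the floor in the doxorubicin control, at 0.12 ± 0.0358 CPM (SD, n = 3; 14 reads over 3 libraries). At 1, 5 and 10 nM it was at -0.78, 0.57 and -0.03, with adjusted p from 0.197 to 0.962. It reached 0.46 ± 0.256 CPM at 15 nM, 139 ± 43.0 at 25 nM, 3030 ± 33.4 at 50 nM and 3710 ± 20.1 at 100 nM. The log2 fold changes were 1.82, 10.12, 14.62 and 14.92 ± 0.42 (SE; limma adjusted p at 100 nM = 1.46e-17). ABCC1, the efflux pump MRP1, moved otherwise: it rose by 1.57 at 15 nM (103 ± 4.48 to 307 ± 28.5 CPM) and at 100 nM it fell by 0.43 (adjusted p = 4.2e-05). ABCG2, another multidrug efflux pump, fell by 3.63 at 15 nM and was at 0.21 at 100 nM (adjusted p = 0.312). TOP2A was at -0.14 at 100 nM (adjusted p = 0.0775), and CDKN1A fell by 0.43 there. The 15 nM call of ABCB1 rests on few reads and was lost with voom on the recovered reads (adjusted p = 0.216). TOP2A at 100 nM passed with replicate blocks (adjusted p = 0.0464) and without control replicate 1 (0.0427).

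At 100 nM doxorubicin IGFBP5, which binds insulin-like growth factors, rose by 5.16 ± 0.18 (SE) from 101 ± 4.77 to 3600 ± 103 CPM (limma adjusted p = 4.31e-16), and MUC16 by 4.70 ± 0.29. The interleukin receptor IL1R1 rose by 3.99 ± 0.14 from 14.3 ± 1.44 to 227 ± 28.3 CPM, and FKBP10, a collagen chaperone, by 3.83 ± 0.14. IGFBP3 rose by 3.53, DHRS2 by 3.19 and TNFRSF11B, the decoy receptor osteoprotegerin, by 3.13. SHH, the secreted hedgehog ligand, fell by 7.88 ± 0.10 (adjusted p = 1.72e-24), from 387 ± 46.3 to 1.64 ± 0.197 CPM, and at 50 nM fell by 8.28. Also lower were the secreted semaphorin SEMA3D at -7.34, the collagen COL12A1 at -6.27, and the autophagy regulator RUBCNL at -5.97. So were protein kinase PRKD3 at -5.87, the cadherin CDH26 at -5.82, the RAS pathway inhibitor SPRED1 at -5.11 and CCN5 at -4.93. ESR1, the estrogen receptor, fell by 0.69 ± 0.07 (417 ± 28.2 to 259 ± 9.70 CPM) and PGR, the progesterone receptor, fell by 2.98 ± 0.14 (116 ± 11 to 14.9 ± 3.65 CPM). The antiapoptotic gene BCL2 rose by 2.43 to 9.34 ± 0.913 CPM.

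Among the lists at 100 nM doxorubicin, 37 of 45 proliferation genes fell and 0 rose, with a median of -0.40 (38 adjusted over the list alone; limma's camera adjusted p = 4.15e-06). Among them were AURKB at -0.78, MCM7 at -0.81 and GINS2 at -0.83. Nuclear genes of the respiratory chain had 21 of 36 down and 3 up (adjusted p = 0.00503), with NDUFA8 at -0.97 and COX8A at -0.83. Of 13 genes of the mitochondrial genome 12 rose and 1 fell (adjusted p = 0.00403), led by MT-CO1 at 1.14 (9330 ± 549 to 20500 ± 628 CPM). Nuclear copies of that genome can share its reads. Homologous recombination and Fanconi genes, which repair double-strand breaks and crosslinks, had 20 of 32 down and 4 up (adjusted p = 0.0339), with XRCC2 at -1.16, FANCC at -0.84 and FANCI at -0.82. Adjusted over the list alone, the counts of the last 3 lists were the same. With an estimated correlation each of these 4 lists had an adjusted p = 0.984. The recombination list also lost its call without control replicate 3 (adjusted p = 0.0616) or 100 nM replicate 1 (0.0592), and the mitochondrial list with quantile normalization (0.0678).

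The other 25 measured lists did not pass at 100 nM doxorubicin, with camera adjusted p from 0.0882 to 0.963. Members up and down, of those measured, were 10 and 5 of 17 ABC transporters (with ABCC5 at 1.15 and MVP at 1.36), 16 and 9 of 35 p53 targets, and 5 and 4 of 15 anthracycline target and metabolism genes. In the lists of chromatin, repair and cell death they were 10 and 3 of 19 histones, 5 and 9 of 18 end joining and mismatch repair genes, and 8 and 6 of 18 BCL2 family genes (9 and 6 adjusted over the list alone). For breast cell identity they were 9 and 14 of 35 estrogen response genes, 7 and 8 of 20 luminal genes (AGR2 at -2.18, AGR3 at -3.45), and 1 and 8 of 15 basal genes. Further pairs were 14 and 5 of 26 junction genes, 3 and 9 of 18 mesenchymal genes, 5 and 5 of 17 stem-like markers, 4 and 3 of 7 ovarian carcinoma markers and 0 and 0 of 3 leukocyte markers. For immunity they were 4 and 5 of 20 antigen presentation genes and 4 and 8 of 19 NF-kB and secreted factor genes. For metabolism they were 10 and 10 of 28 folate genes (11 and 10 adjusted over the list alone), 8 and 6 of 26 amino acid carriers, 8 and 7 of 27 ATF4 and unfolded protein genes, and 5 and 10 of 25 NRF2 targets. Lysosomal and other metabolic lists had 10 and 15 of 35 lysosomal genes (10 and 16 adjusted over the list alone), 9 and 8 of 24 cholesterol genes (10 and 8 adjusted over the list alone), 12 and 12 of 27 glycolysis genes and 24 and 6 of 43 ribosomal protein genes. Where no second pair is given, the counts adjusted over the list alone were the same. Median, mean and test differed in sign for the anthracycline list (-0.04, 0.24, up), the luminal list (0.01, -0.33, down), the glycolysis list (-0.08, 0.18, down) and the cholesterol list (0.04, -0.07, up). The interferon, NF-kB and amino acid carrier lists had medians of 0.00 with means of -0.21, -0.19 and -0.02, and the test of the carriers pointed up.

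At 1 nM epirubicin the apoptosis inhibitor BCL2 rose by 3.77 ± 0.15 (SE) from 1.16 ± 0.0942 to 15.8 ± 0.703 CPM (limma adjusted p = 8.55e-14). ABCA12, a lipid transporter of keratinocytes, rose by 2.99 ± 0.21 from 4.45 ± 0.618 to 35.7 ± 6.43 CPM. NR4A3 fell by 4.90 at 1 nM (180 ± 19.4 to 6.73 ± 4.10 CPM), fell by 3.30 at 5 nM and fell by 4.42 at 10 nM. MAFF, a small basic leucine zipper factor, fell by 4.33 at 1 nM. At 5 nM ABCA12 and GPNMB each rose by 2.41, and RIPK4, a kinase of epidermal differentiation, fell by 2.59. All 43 ribosomal protein genes fell at 1 nM, with a median of -0.43 (43 adjusted over the list alone; camera adjusted p = 7.56e-13, adjusted p = 0.689 with an estimated correlation). The epirubicin controls stood high for that list, with mean log2 CPM of 9.67, 9.5 and 9.77, against 9.21, 9.24 and 9.21 at 1 nM. The doxorubicin controls, from the separately normalized table, had 9.31, 9.3 and 9.23. The NF-kB and secreted factor list fell, 11 of 18 down and 1 up with a median of -1.36 (same counts adjusted over the list alone; adjusted p = 9.09e-05, adjusted p = 0.1 with an estimated correlation). Recombination and Fanconi genes rose, 19 of 32 with 0 down (19 and 1 adjusted over the list alone; adjusted p = 0.000711, adjusted p = 0.689 with an estimated correlation). At 5 nM 23 of 35 p53 targets rose and 1 fell (same counts adjusted over the list alone; adjusted p = 1.29e-07, adjusted p = 0.121 with an estimated correlation). Of 17 ABC transporters 9 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.00392, adjusted p = 0.469 with an estimated correlation).

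At 10 nM epirubicin 39 of 40 interferon-stimulated genes rose and 0 fell, with a median of 4.06 (39 adjusted over the list alone; limma's camera adjusted p = 4.53e-13, adjusted p = 0.518 with an estimated correlation). IFI6 rose by 7.02 ± 0.43 (SE), from 7.28 ± 1.96 to 931 ± 115 CPM, and PARP10 by 6.08 ± 0.39, from 1.11 ± 0.314 to 73.5 ± 5.13 CPM. Antigen presentation genes had 16 of 19 up and 1 down (same counts adjusted over the list alone; adjusted p = 4.39e-06, adjusted p = 0.518 with an estimated correlation). At 15 nM the interferon list had 36 of 40 up and 1 down, with a median of 2.85 (same counts adjusted over the list alone; adjusted p = 7.51e-08, adjusted p = 0.55 with an estimated correlation). The libraries stood apart there, with list medians of 4.22, 2.24 and 2.51 above the control mean in replicates 1, 2 and 3. At 100 nM 14 members rose and 9 fell (same counts adjusted over the list alone; adjusted p = 0.778).

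At 15 nM epirubicin GPNMB rose by 6.71 ± 0.26 (SE), from 1.93 ± 0.518 to 198 ± 17.5 CPM (limma adjusted p = 1.68e-15). TNFRSF11B rose by 6.34 ± 0.15, from 2.39 ± 0.325 to 193 ± 24.9 CPM. CCN5 fell by 6.40 and the chemokine CXCL12 fell by 5.22. CDKN1A rose by 1.42 to 514 ± 13 CPM from 193 ± 18.3, and ABCC1 by 1.90 to 380 ± 33.3 CPM from 102 ± 12.7. TOP2A fell by 1.46 to reach 150 ± 6.60 CPM from 412 ± 16.9. The p53 targets had 24 of 35 up and 5 down (24 and 6 adjusted over the list alone; camera adjusted p = 0.00107, adjusted p = 0.55 with an estimated correlation). Proliferation genes had 43 of 45 down and 0 up, with a median of -0.99 (44 adjusted over the list alone; adjusted p = 8.91e-12, adjusted p = 0.55 with an estimated correlation). Basal genes, markers of another breast cell type, rose at this dose, 14 of 18 with 4 down (same counts adjusted over the list alone; adjusted p = 0.0136, adjusted p = 0.55 with an estimated correlation).

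From 25 nM epirubicin ABCB1 had the largest rise of the genes past the test and the level minimum. From 0.20 ± 0.00916 CPM in the control (SD, n = 3; 22 reads over 3 libraries) it reached 1560 ± 65.8 at 25 nM, 1470 ± 28.2 at 50 nM and 1900 ± 153 at 100 nM. The log2 fold changes were 12.91, 12.82 and 13.19 ± 0.21 (SE; limma adjusted p at 100 nM = 1.17e-22). At 1 nM, with 10 reads over 3 libraries, ABCB1 was at -1.24 (adjusted p = 4.84e-05), a call lost with 1 CPM added (0.0908) and with only the compared groups fitted (0.0716). At 5 nM it was at 0.48 (0.0595), and passed without 5 nM replicate 3 (0.00971). At 10 and 15 nM, also with few reads, it was at 0.30 (adjusted p = 0.203) and 1.04 (adjusted p = 0.000108). With quantile normalization these values turned to -1.10, which passed (0.00571), and -0.11, which did not (0.776). At 100 nM GPNMB rose by 3.80, the germline tudor protein TDRD1 by 3.79 (1.01 ± 0.241 to 13.8 ± 0.257 CPM), the sialyltransferase ST8SIA6 by 3.22 and ABCA12 by 3.16. Further rises were those of C14orf132 by 3.04, the protease CAPN2 by 2.86 and IL17RE, a receptor of interleukin 17C, by 2.77. NR4A3 fell by 6.65 ± 0.75 (180 ± 19.4 to 4.71 ± 6.87 CPM, adjusted p = 6.87e-08). The cadherin CDH26 was at -4.88, TMTC1 at -4.23, the membrane metalloproteinase MMP16 at -4.22, the protease inhibitor TFPI2 at -4.10, the WNT target AXIN2 at -4.03, the calcitonin receptor CALCR at -3.90 and SYBU at -3.83. CDKN1A was at 0.02 (adjusted p = 0.882), MDM2 at 0.05 (0.444), TOP2A at 0.02 (0.84) and ABCC1 at -0.07 (0.454). TOP2B rose by 0.39, ABCG2 fell by 1.62 and ESR1 was at -0.27, and at -0.17 without control replicate 2.

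Among the lists at 100 nM epirubicin, 30 of 36 nuclear respiratory chain genes fell and 0 rose, with a median of -0.48 (limma's camera adjusted p = 1.15e-06), with COX6C at -1.23 and UQCRFS1 at -0.94. Ribosomal protein genes had 27 of 43 down and 2 up (adjusted p = 0.00935), with RPL6 at -0.69, and their pseudogene copies make single members uncertain. Proliferation genes had 27 of 45 down and 2 up (adjusted p = 0.00935), with MYBL2 at -1.05 and TK1 at -1.01. Junction genes, which hold epithelia together, had 19 of 26 up and 4 down (adjusted p = 0.018), with the desmosomal cadherin DSC2 at 2.20 and LAD1 at 0.85. The NF-kB and secreted factor list had 12 of 18 down and 1 up (adjusted p = 0.0376), with TNFAIP3 at -2.72, IGFBP3 at -1.80 and RELB at -1.54. Adjusted over the list alone, the counts of these 5 lists were the same, and with an estimated correlation each had an adjusted p = 0.942. In 100 nM replicate 3 the mean log2 CPM of the proliferation list was 5.99, against 6.31 and 6.48 in the others, and the call was lost without it (adjusted p = 0.12). The ribosomal call was lost without control replicate 3 (0.0521). The mean log2 CPM of that list was 9.31, 9.36 and 9.5 at 100 nM, against 9.67, 9.5 and 9.77 in the controls. The NF-kB call was lost without control replicate 1 (0.069) or 3 (0.0608), without 100 nM replicate 2 (0.0574) or 3 (0.0654) and with voom (0.0566). With quantile normalization both this list (0.0516) and the ribosomal list (0.264) missed the threshold.

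The other 24 measured lists did not pass at 100 nM epirubicin, with camera adjusted p from 0.379 to 0.972. Members up and down were 8 and 4 of 17 ABC transporters (ABCB4 at 2.85), 6 and 3 of 15 anthracycline target and metabolism genes, and 13 and 11 of 35 p53 targets. In chromatin, repair and cell death they were 1 and 5 of 17 histones, 14 and 8 of 32 recombination and Fanconi genes (ATM at 1.16), 5 and 5 of 18 end joining and mismatch repair genes and 7 and 5 of 18 BCL2 family genes. For cell identity they were 11 and 17 of 35 estrogen response genes, 8 and 9 of 21 luminal genes (TFAP2A at -2.88, MUC1 at 1.01), and 7 and 4 of 18 basal genes. Mesenchymal and other markers had 3 and 6 of 18 mesenchymal genes (SNAI2, a transcription factor of mesenchymal transition, from 47.1 ± 2.98 to 0.664 ± 0.347 CPM), 6 and 10 of 17 stem-like markers (SOX9 at -3.03), 3 and 1 of 6 ovarian carcinoma markers and 1 and 2 of 3 leukocyte markers. Antigen presentation had 6 and 4 of 19. For metabolism they were 11 and 5 of 28 folate genes, 11 and 4 of 25 amino acid carriers, 9 and 10 of 27 ATF4 and unfolded protein genes, and 6 and 12 of 25 NRF2 targets (6 and 13 adjusted over the list alone). Lysosomal and other metabolic lists had 7 and 14 of 35 lysosomal genes (6 and 13 adjusted over the list alone), 8 and 7 of 24 cholesterol genes and 6 and 12 of 26 glycolysis genes. Genes of the mitochondrial genome had 3 up and 1 down of 13 (0 and 0 adjusted over the list alone). Their mean log2 CPM was 10.62 in control replicate 2 against 11.45 and 11.83 in the other controls. Counts adjusted over the list alone were the same elsewhere, and only for antigen presentation did the median (0.09) differ in sign from the mean (-0.32) and the test.

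**Figure D3:**
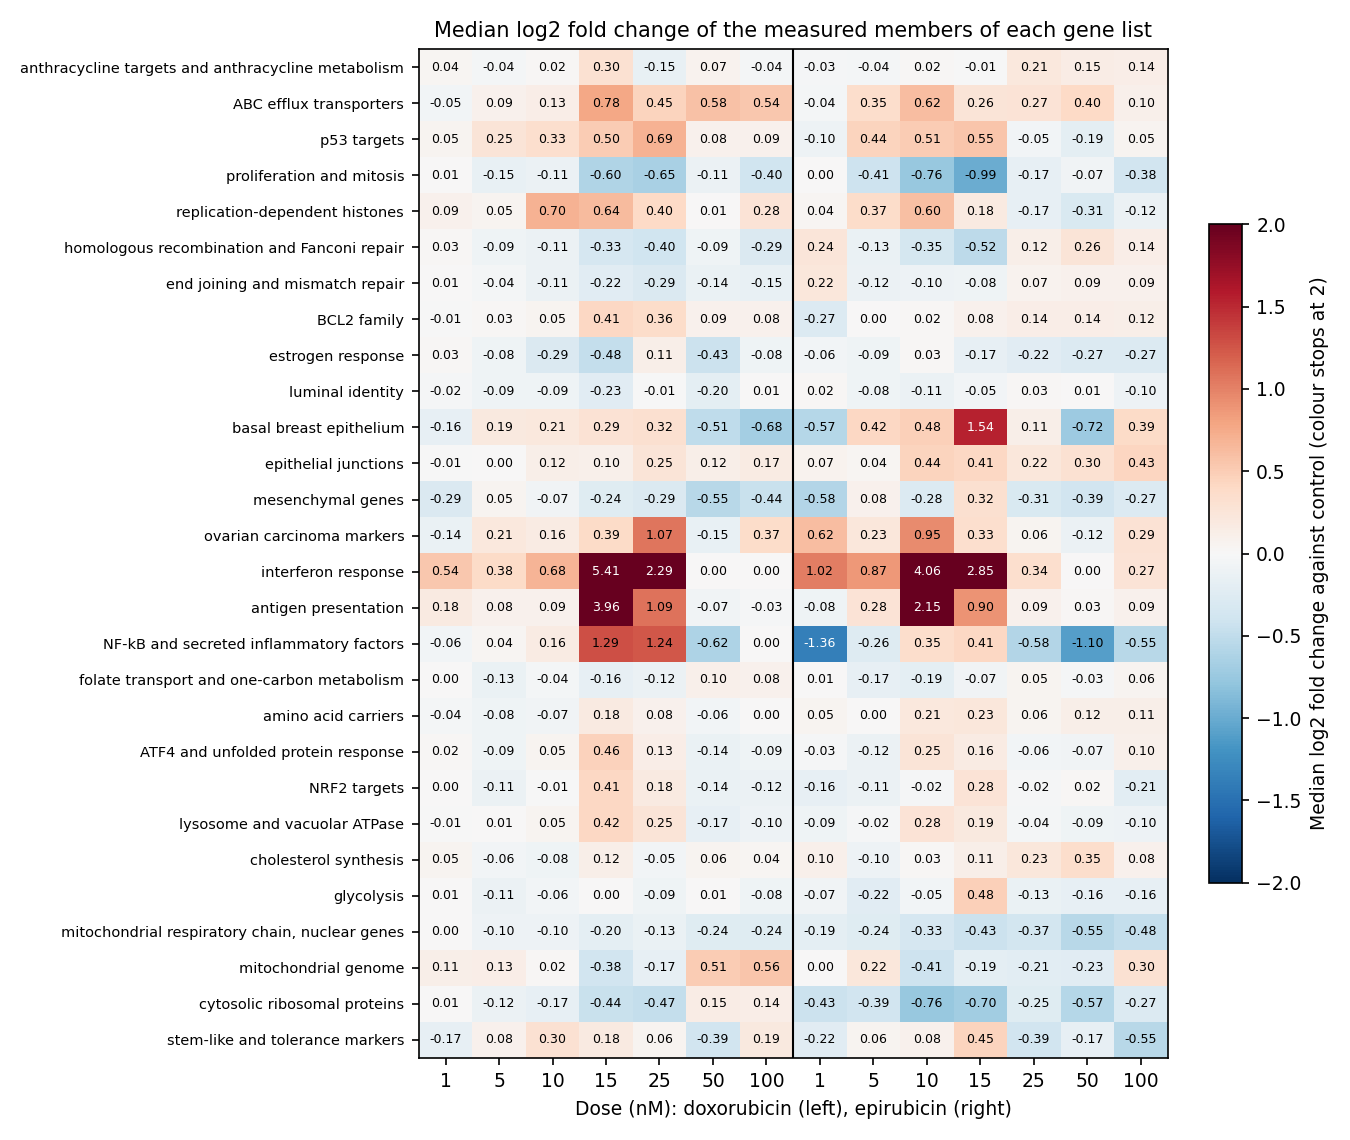
Median log2 fold change of the measured members of 28 gene lists at each dose in nM against the drug's own control, with the colour scale ending at 2. The interferon list reads 5.41 at doxorubicin 15 nM and 4.06 at epirubicin 10 nM, and 0.00 and 0.27 at 100 nM.

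Doxorubicin and epirubicin were compared at matched doses by the difference of their changes, each taken within its own table, since the tables were normalized separately. At 100 nM the lowest differences among genes that met the naming rule were those of SHH, with -6.85 (95% interval -7.21 to -6.50), COL12A1 with -6.82 (-7.48 to -6.16) and ABCA12 with -6.68 (-7.30 to -6.06). Next were the heparan sulfatase SULF1 with -5.95, PRKD3 with -5.92 and SPRED1 with -5.35, each lower under doxorubicin relative to its control than under epirubicin. Higher under doxorubicin by the same rule were NR4A3, with 6.77 (4.40 to 9.14, limma adjusted p = 5.31e-06), the surface antigen PSCA with 5.85, the Rho family GTPase RND1 with 5.42, IGFBP3 with 5.33, IGFBP5 with 4.61 and RIPK4 with 4.42. NR4A3 was at 237 ± 74.2 CPM at doxorubicin 100 nM and 217 ± 63.7 in its control, but between 3 and 28.9 CPM on average at the lower doses. Same-numbered libraries of that control and dose deviated together, with correlations across genes of 0.31 to 0.55, and whether they were handled together is not given in the sources used here. ABCB1 rose more under doxorubicin, by 1.73 (0.73 to 2.73, adjusted p = 0.00274). ABCG2 differed by 1.83 (1.3 to 2.36), CDKN1A by -0.45, ESR1 by -0.41, ABCC1 by -0.36 and MDM2 by 0.26. TOP2A differed by -0.16 (-0.36 to 0.04, adjusted p = 0.167), TOP2B by -0.16 (-0.34 to 0.01, adjusted p = 0.102) and MKI67, the Ki-67 antigen, by -0.11 (-0.51 to 0.29, adjusted p = 0.653). In all, 7702 of 12659 genes differed at 100 nM, 3808 above 0 and 3894 below. With voom on the recovered reads the ABCB1 difference missed the threshold (adjusted p = 0.0994), and TOP2B passed it without epirubicin control replicate 2 (0.0253), without epirubicin 100 nM replicate 2 (0.0412) or with quantile normalization (0.0499).

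Of the lists, ribosomal protein genes lay higher under doxorubicin at 100 nM, 32 of 43 above 0 and 1 below, with a median difference of 0.36 (same counts adjusted over the list alone; limma's camera adjusted p = 0.000326, adjusted p = 0.962 with an estimated correlation). RPL6 was at 0.95 and RPL11 at 0.82. The mean log2 CPM of the ribosomal list was 9.67, 9.5 and 9.77 in the epirubicin controls, against 9.31, 9.3 and 9.23 in the doxorubicin controls. At 100 nM it was 9.41, 9.36 and 9.36 under doxorubicin and 9.31, 9.36 and 9.5 under epirubicin. As far as levels of separately normalized tables can be compared, the ribosomal difference thus leans on the controls. Recombination and Fanconi genes lay lower under doxorubicin, 20 of 32 below 0 and 2 above, with a median of -0.36 (21 and 2 adjusted over the list alone; adjusted p = 0.00632, adjusted p = 0.962 with an estimated correlation). FANCB was at -2.20 and XRCC2 at -1.61. The other 27 measured lists had adjusted p from 0.0699, for basal genes and for the nuclear respiratory chain, to 0.967. Median, mean and test differed in sign for the anthracycline (0.02, 0.17, down), ABC transporter (-0.02, 0.26, up), p53 (-0.14, 0.08, up), estrogen response (-0.24, 0.02, up), mesenchymal (0.10, -0.14, down) and lysosomal lists (0.01, -0.10, up). Single members still differed widely, among them SNAI2 at 5.83, SOX9 at 4.34, PGR at -2.67, GSTM3 at 2.52 and MUC1 at -2.17. The ribosomal call was lost with quantile normalization (adjusted p = 0.0595). Basal genes passed when only the compared groups were fitted (0.0302) and without doxorubicin 100 nM replicate 3 (0.0439) or epirubicin 100 nM replicate 2 (0.0412). The nuclear respiratory chain passed without either of these (0.039 and 0.0365) or without epirubicin control replicate 2 (0.0135), and the mitochondrial genome without that control (0.0083).

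**Figure D4:**
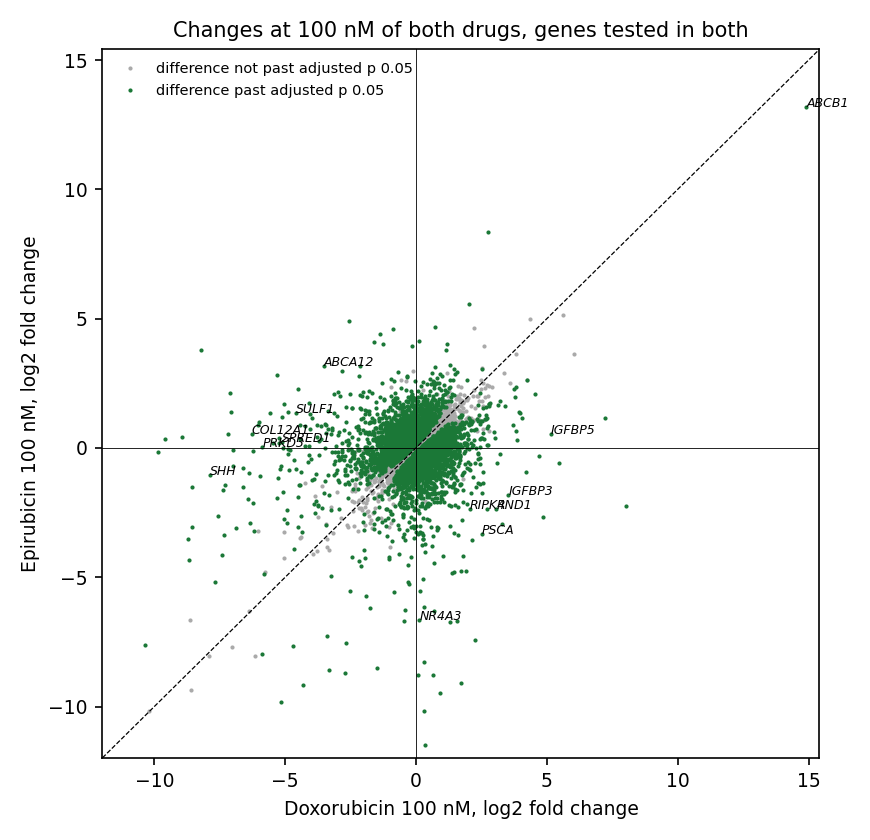
Log2 fold change at 100 nM of doxorubicin (x axis) against epirubicin (y axis), each against its own control, for the genes tested in both tables, with green points for the 7702 genes whose difference passed the adjusted p threshold. ABCB1 lies at 14.92 and 13.19, and SHH and NR4A3 lie far from the diagonal.

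At lower doses the drugs differed in 2041 genes at 1 nM, 1080 at 5 nM, 6679 at 10 nM, 6446 at 15 nM, 7219 at 25 nM and 7055 at 50 nM (limma, 12659 genes). The interferon list separated them at 10 nM, where 38 of 40 members lay below 0 with a median difference of -3.39 (39 adjusted over the list alone; camera adjusted p = 1.21e-18, adjusted p = 0.213 with an estimated correlation). IFI6 was at -6.18. They differed the other way at 15 nM, where 38 lay above 0 with a median of 2.67 (38 adjusted over the list alone; adjusted p = 5.41e-11, adjusted p = 0.316 with an estimated correlation). The epirubicin libraries stood apart there, with list medians of 4.22, 2.24 and 2.51 above the control mean, against 5.33, 5.53 and 5.38 under doxorubicin. At 25 nM p53 targets lay higher under doxorubicin, 28 of 35 above 0 and 1 below with a median of 0.79 (same counts adjusted over the list alone; adjusted p = 1.68e-08, and adjusted p = 0.0388 with an estimated correlation). CDKN1A was at 2.25 (95% interval 2 to 2.51) and ABCB1 at -2.79 (-3.79 to -1.78). The NF-kB list lay higher there too, 13 of 17 above 0 and 1 below (same counts adjusted over the list alone; adjusted p = 0.000201, and adjusted p = 0.0388 with an estimated correlation). PSCA differed by 6.41 and PLEKHS1 by -4.03 at 25 nM, PLEKHS1 by 4.59 and CCDC85A by -5.23 at 15 nM, and CDH26 by 3.04 at 10 nM. At 50 nM IGFBP5 differed by 5.91, SHH by -8.58 and ABCB1 by 1.81 (adjusted p = 0.00209, and 0.091 with voom). Low-dose counts leaned on single libraries. At 1 nM 1036 genes differed without epirubicin control replicate 3, 1302 without epirubicin 1 nM replicate 3, 1346 without doxorubicin control replicate 3 and 1353 without doxorubicin 1 nM replicate 3. At 5 nM 711 differed without doxorubicin control replicate 3 and 458 with only the compared groups fitted.

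Many genes moved the same way under both drugs at a matched dose. At 1 nM 952 genes were up under both and 822 down, against 316.7 and 299.6 for independent lists of those sizes. At 5 nM 1297 and 1241 were shared against 387.7 and 386.7, at 10 nM 1947 and 1788 against 1010.2 and 998.8, and at 15 nM 3023 and 3170 against 1664.9 and 1700.7. At 25 nM 2219 and 2187 were shared against 1461.4 and 1444.3, at 50 nM 2362 and 2303 against 1512.9 and 1434.9. At 100 nM 2225 and 2207 were shared against 1557.8 and 1463.3, while 870 genes were up under doxorubicin and down under epirubicin and 905 the reverse, against 1513.6 and 1506.1 for independent lists. Among genes changed at least 2-fold under both drugs at 100 nM, 211 and 224 were shared against 47.4 and 44.7, and 64 and 67 moved in opposite directions against 44.3 and 47.8. At 25 nM 110 such genes were up under doxorubicin and down under epirubicin against 52.5, and 24 the reverse against 28.1. Across 10784 genes, which are not independent replicates, Pearson's r between the drugs' log2 fold changes was 0.74 at 1 nM, 0.80 at 5 nM, 0.56 at 10 nM, 0.69 at 15 nM, 0.41 at 25 nM, 0.49 at 50 nM and 0.36 at 100 nM. Among the 49 pairs of doses, doxorubicin 25 nM had r = 0.73 with epirubicin 15 nM.

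Genes called at a lower dose were looked up at 100 nM of the same drug, where all doses share the control libraries. Under doxorubicin 78.0% of the genes up and 78.9% of those down at 50 nM were called the same way at 100 nM. The shares were 49.0% and 47.5% of those at 25 nM, 44.3% and 45% at 15 nM, 49.2% and 46.8% at 10 nM, 51.2% and 50.8% at 5 nM, and 42.9% and 36.9% at 1 nM. Under epirubicin they were 80.2% and 78.7% of those at 50 nM, 89.6% and 88.3% at 25 nM, 59.0% and 58.1% at 15 nM, 60.2% and 59.8% at 10 nM, 59.9% and 58.2% at 5 nM, and 65.1% and 59.7% at 1 nM. In counts, 3564 genes were up at both 50 and 100 nM doxorubicin against 1624.8 for independent lists, and 3774 at both 25 and 100 nM epirubicin against 1464.1. Of the genes at doxorubicin 1 nM, 573 were up at both doses against 475.2 for independent lists and 489 down at both against 449.1, while 324 and 459 were called the opposite way at 100 nM. Simulated groups with no change against the same controls shared 0 genes, a value that does not measure what shared controls add to the overlap of real changes. The 3 control libraries of a drug cannot be divided into parts of at least 2, so part of the excess may come from the shared controls, and the differences between these percentages were not tested.

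The ABCB1 locus was read against its neighbours. Within 1 Mb, 11 other genes were tested, and their median log2 fold change at 100 nM was -0.19 under doxorubicin, 5 of them up and 5 down. It was -0.17 under epirubicin, with 4 up and 4 down (limma). At 25 nM the medians were 0.07 and -0.14, and at 50 nM -0.34 and 0.00. ABCB4, the adjacent paralog that moves phospholipids into bile, rose by 1.49 ± 0.32 (SE) under doxorubicin and 2.85 ± 0.30 under epirubicin at 100 nM, but from 0.663 and 0.254 CPM to 1.83 and 1.81 CPM. The body of RUNDC3B overlaps that of ABCB1, so its own count is uncertain.

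**Figure D5:**
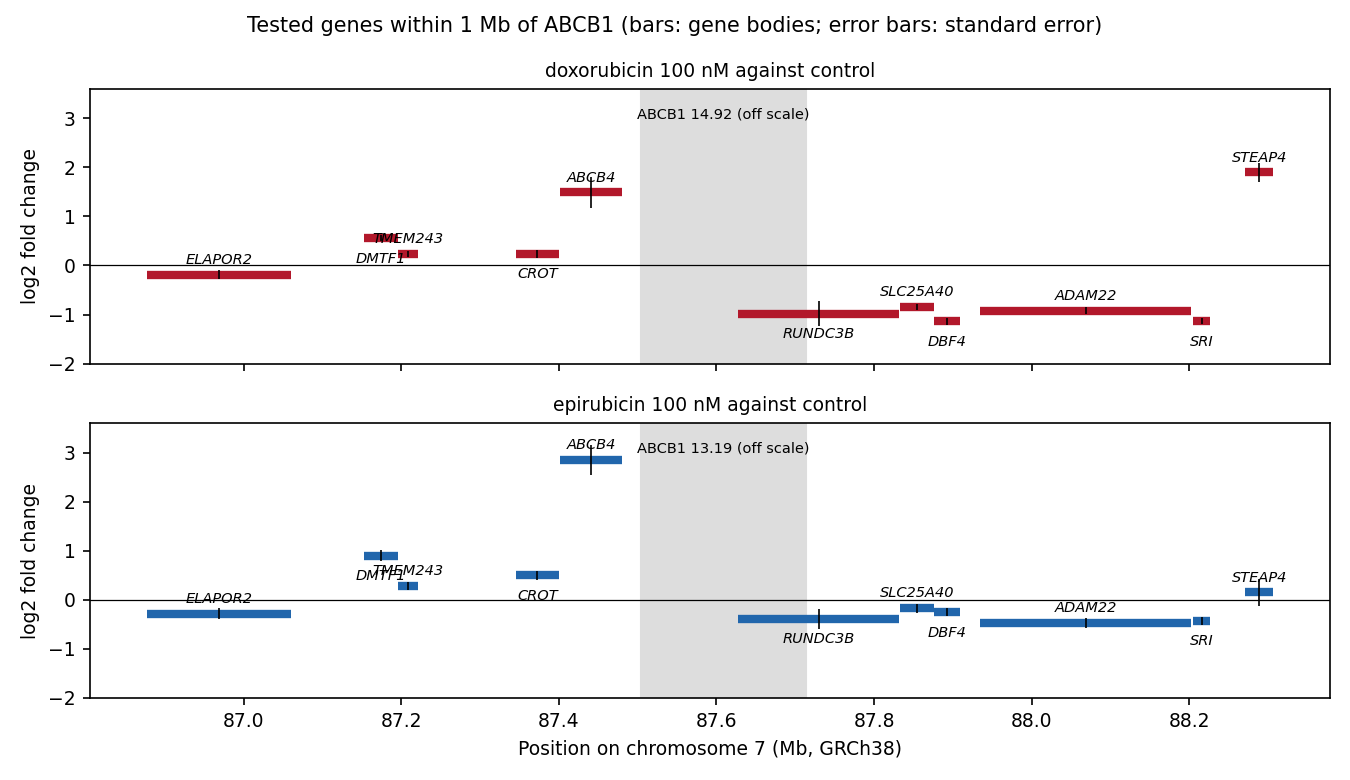
Gene bodies (bars) on chromosome 7 within 1 Mb of ABCB1 against log2 fold change at 100 nM with SE, under doxorubicin and epirubicin, with ABCB1 itself off the scale. The other 11 genes have medians of -0.19 and -0.17, and ABCB1 stands at 14.92 and 13.19.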

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

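Tests of the scaling of the libraries and of blood cells, the sorting of the splits by how far they exchange control and dose, and the exchange of treated libraries between the drugs were chosen after the results were seen. Each value here is a doxorubicin change minus an epirubicin change on the log2 scale, reported because the test of the difference itself passed (limma, adjusted over 12659 genes at a dose).

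At 1 nM 2041 genes differed between the drugs, with ABCA12 at -2.09, CDKN1A at 0.40, ESR1 at -0.44, GEM, a small GTP-binding protein, at 2.50, MDM2 at -0.22, SLC38A7 at 0.36 and SLC46A1 at -0.37. At 5 nM 1080 genes differed, with ABCA12 at -1.88, MDM2 at -0.38 and SCIN, an actin-severing protein, at 1.36. At 10 nM 6679 genes differed, with ABCC1 at -0.98, ABCG2 at -0.76, CDH26 at 3.04, IFI6 at -6.18, MDM2 at -0.48, MKI67 at 0.57, SLC38A7 at -0.67, SLC46A1 at -0.46 and TOP2A at 0.54. At 15 nM 6446 genes differed, with ABCC1 at -0.33, ABCG2 at -2.99, CCDC85A at -5.23, CDKN1A at -0.65, ESR1 at 0.44, MDM2 at -0.33, PLEKHS1 at 4.59, SLC46A1 at -0.28, TOP2A at 0.40 and TOP2B at -0.23.

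At 25 nM 7219 genes differed, with ABCB1 at -2.79, ABCC1 at 0.59, CDKN1A at 2.25, ESR1 at -0.59, MDM2 at 0.84, MKI67 at -0.89, PLEKHS1 at -4.03, PSCA at 6.41, SLC46A1 at -0.51, TOP2A at -1.36 and TOP2B at -1.29. At 50 nM 7055 genes differed, with ABCB1 at 1.81, CDKN1A at -0.31, ESR1 at -0.92, IGFBP5 at 5.91, SHH at -8.58, SLC46A1 at -0.82 and TOP2B at -0.23. At 100 nM 7702 genes differed, with ABCA12 at -6.68, ABCB1 at 1.73, ABCC1 at -0.36, ABCG2 at 1.83, CDKN1A at -0.45, COL12A1 at -6.82, ESR1 at -0.41, IGFBP3 at 5.33, IGFBP5 at 4.61, MDM2 at 0.26, NR4A3 at 6.77, PRKD3 at -5.92, PSCA at 5.85, RIPK4 at 4.42, RND1 at 5.42, SHH at -6.85, SLC46A1 at -0.84, SPRED1 at -5.35 and SULF1 at -5.95. Of the lists, recombination and Fanconi repair (adjusted p = 0.00632) and ribosomal proteins (0.000326) differed at 100 nM, and with an estimated correlation both had an adjusted p = 0.962.

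Several of these calls ended under other settings. At 1 nM GEM ended in 13 (adjusted p from 0.0508 to 0.143), namely 1 CPM added, eBayes without trend, only the groups compared, quantile normalization, and without any doxorubicin control, doxorubicin 1 nM replicate 2 or 3, epirubicin control replicate 1 or 3 or epirubicin 1 nM replicate 1 or 3. MDM2 at 1 nM ended in 8 (0.0558 to 0.166), namely only the groups compared, quantile normalization, and without doxorubicin control replicate 1 or 3, doxorubicin 1 nM replicate 1 or 3, epirubicin control replicate 3 or epirubicin 1 nM replicate 1. CDKN1A at 1 nM ended without doxorubicin control replicate 2, epirubicin control replicate 1 or 3 or epirubicin 1 nM replicate 3 (0.07 to 0.0802). SLC38A7 and SLC46A1 at 1 nM ended in 8 (0.0506 to 0.0832) and 5 settings (0.0503 to 0.0724), and SLC46A1 at 15 nM in 9 (0.05 to 0.194), as given in their own accounts. At 10 nM ABCG2 ended without doxorubicin control replicate 3, epirubicin control replicate 1 or epirubicin 10 nM replicate 1 (0.0638 to 0.0752), and MKI67 without epirubicin control replicate 2 or epirubicin 10 nM replicate 1 (0.0601 to 0.0885). At 15 nM ABCC1 ended without doxorubicin 15 nM replicate 1 or epirubicin control replicate 3 (0.0522 to 0.0682). TOP2B at 15 nM ended without doxorubicin control replicate 3, doxorubicin 15 nM replicate 1, epirubicin control replicate 3 or epirubicin 15 nM replicate 3 (0.0638 to 0.0964). CDKN1A at 50 nM ended in 7 (0.0654 to 0.122), namely quantile normalization, and without doxorubicin control replicate 1 or 3, doxorubicin 50 nM replicate 2 or 3, epirubicin control replicate 2 or epirubicin 50 nM replicate 1. TOP2B at 50 nM ended without control replicate 3 of either drug (0.0763 to 0.101), and ABCB1 with voom at 50 nM (0.091) and 100 nM (0.0994).

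For the counts, the 6 treated libraries of a dose, each set against its own control mean, were exchanged between the drugs. These splits number 10, too few for a share under 0.05. The error of a control mean also shifts all treated libraries of its drug alike. This favours the real split even if both drugs act alike, so these splits decide nothing on that. Of them 1, the real one, gave the most genes at each dose, 2041, 1080, 6679, 6446, 7219, 7055 and 7702 from 1 to 100 nM, and the highest others were 0, 0, 0, 1, 0, 0 and 0. In 100 splits of control and dose within each drug, 8, 11, 8, 10, 3, 3 and 2 gave as many genes as the real one, with highest others of 6135, 7176, 8933, 10147, 9369, 9437 and 9378. The highest exchanges control and dose of epirubicin, which turns the difference into a sum. Among the 37 splits that mostly exchange neither drug the highest others were 3060, 3400, 6914, 5054, 5106, 5158 and 5847, above the real count at 1, 5 and 10 nM. Each such split also takes away part of a drug's own effect, so these 100 splits are no test of equal effects of both drugs.

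ABCB1 rose by over 10 log2 units from 25 nM under both drugs. Reads shared with ABCB4 are argued against, since ABCB4 stood at no more than 0.806% of the ABCB1 CPM in any group at 25 nM and above. Gain of copies of the whole region within 1 Mb is argued against as well, since the median change of its 11 other tested genes was as low as -0.34 and never above 0.07 at these doses. That median joins genes that rose and genes that fell. DMTF1, TMEM243, CROT and ABCB4, which lie together before ABCB1, each rose at 100 nM under both drugs. At epirubicin 25 nM they also rose, by 0.87, 0.38, 0.43 and 2.87. They did not follow ABCB1 at every dose. At doxorubicin 25 nM, with ABCB1 at 10.12, they were at -0.03, 0.07, 1.44 and 0.71, and only CROT passed. CROT was at 1.16 at epirubicin 15 nM, where ABCB1 stood at 0.42 CPM. A gain confined to fewer genes, or a change of transcription that came with the dose, may still account for the rise of ABCB1 and was not tested.

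By group median, interferon-stimulated genes peaked at 15 nM doxorubicin and 10 nM epirubicin. At 15 nM epirubicin replicate 1, with a list median of 4.22, lay above the 10 nM libraries (4.12, 3.99 and 4.07), and replicates 2 and 3 were at 2.24 and 2.51. The median change of all tested genes was within 0.009 of 0 in both peak contrasts. Scaling applied before the test brings that median near 0, so by itself it decides nothing on the scaling of the libraries. A shift of whole libraries would move all genes alike, while the list medians of the 6 libraries at the peak doses were at 3.99 or more. Blood cells in the cultures are argued against by leukocyte markers, of which the highest, CD8A, reached 2.17 CPM in the 6 libraries. A single library is argued against too, since the lowest list median among the 6 was 3.99 above the control mean. A response of the cells at these doses may account for it as a hypothesis, and other conditions of the culture were not tested.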

How the results depend on the processing

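Voom on the recovered reads was chosen after the results were seen, and all other settings before. Among results of named genes, library medians, eBayes without trend, 1 CPM added and no filter left 599, 600, 599 and 602 on the same side of the threshold, quantile normalization ended 13 calls, added 6 and reversed the sign of 2 further results, only the groups compared ended 15 and added 1, and voom ended 8. Leaving out a library ended 116 calls of single genes, added 20 and left 4418 the same. The reversed results were those of ABCB1 under epirubicin, both with few reads. At 10 nM it turned from 0.30 to -1.1, which then passed (limma adjusted p = 0.00571). At 15 nM it turned from 1.04 to -0.11, where the call ended (0.776). The replicate block passed TOP2A at doxorubicin 100 nM (adjusted p = 0.0464) and changed no other call. Of 87 camera tests at 100 nM 11 passed, and with an estimated correlation 0 of these 11 did, as given with each list. Leaving out a library ended 8 and added 6. With fry's directional test 42 lists more passed, and 71 with its mixed test. Fry does not set a list against other genes, and 69.5%, 68.2% and 60.8% of all genes passed for doxorubicin, epirubicin and the difference at 100 nM. These passes thus show no change particular to a list. The share of higher calls stayed between 43.6% and 57.7%, and no scaling moved the median of all genes by over 0.061. Members at 0 to 3 reads stood in 57 of 406 list medians, and setting them to their bound moved a median by at most 0.38 and turned 0 signs.

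Counts of calls of any size stayed within 1.5 times except at 1 and 5 nM. Counts of 2-fold calls dropped by more than that in 14 of 21 comparisons with 1 CPM added, among them doxorubicin 100 nM with 985 against 1629 and epirubicin 100 nM with 1011 against 1616, and in 4 of 21 with the stricter filter. The difference at 5 nM gave 458 genes with only the groups compared (412 of them shared). Leaving out 1 library gave 1665 to 2651 calls at doxorubicin 1 nM, 1800 to 2957 at doxorubicin 5 nM, 1036 to 2975 for the difference at 1 nM and 711 to 1301 at 5 nM. With 1 library left out, the calls at 100 nM were 8420 to 8560 for doxorubicin, 8206 to 8601 for epirubicin and 7330 to 7682 for the difference. Of genes changed at least 2-fold, 74 were up and 124 down under both drugs at 1 nM, 92 and 46 at 5 nM, 198 and 84 at 10 nM, 689 and 380 at 15 nM, 230 and 179 at 25 nM, 234 and 301 at 50 nM and 211 and 224 at 100 nM, since a stricter call takes fewer genes. Of 2-fold calls, those called the same way and 2-fold at 100 nM were 27.7% of those up and 17.2% of those down at doxorubicin 1 nM, 13.8% of those down at 5 nM, 20.4% and 21.1% at 15 nM and 30.3% and 27.4% at 25 nM, and 34.8% and 39.6% at epirubicin 10 nM and 34% and 36.1% at 15 nM. The cause of the other changes was not tested. Depth limits ABCB1 at every dose and in the difference between the drugs, since 14 and 22 control reads are the baseline of its changes.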

Other observations

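The tests of control library depth and of libraries handled together were chosen after the results were seen, as were the ratio without 100 nM, the ranges over libraries, the genes of the ABCB1 region and the genes named for their levels in the controls. Gene lists at doses below 100 nM were tested after the data were examined.

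Cholesterol genes, of the mevalonate pathway and its sterol-regulated partners, rose at 50 nM epirubicin, 14 of 24 with 2 down and a median of 0.35 (same counts adjusted over the list alone; limma's camera adjusted p = 0.0194, adjusted p = 0.924 with an estimated correlation). They differed between the drugs there, 16 lying lower under doxorubicin and 1 higher (same counts adjusted over the list alone; adjusted p = 0.00356, adjusted p = 0.981 with an estimated correlation). Glycolysis genes rose at 15 nM epirubicin, 18 of 26 with 4 down and a median of 0.48 (same counts adjusted over the list alone; adjusted p = 0.00582, adjusted p = 0.55 with an estimated correlation). Ribosomal protein genes lay higher under doxorubicin at 1 nM, 42 of 43 with 0 lower (42 adjusted over the list alone; adjusted p = 2.71e-25, adjusted p = 0.343 with an estimated correlation). They also did at 5, 10 and 15 nM (adjusted p = 6.26e-13, 1.41e-13 and 0.00246, and with an estimated correlation adjusted p = 0.816, 0.579 and 0.806), where 11, 41 and 23 lay higher and 0 lower (20, 41 and 23 adjusted over the list alone). At 25 nM it was the other way, 22 lower and 1 higher (same counts adjusted over the list alone; adjusted p = 0.00959, adjusted p = 0.779 with an estimated correlation). At 50 nM they again lay higher, 38 with 0 lower (39 adjusted over the list alone; adjusted p = 2.5e-14, adjusted p = 0.981 with an estimated correlation). The epirubicin controls stood high, at list means of 9.67, 9.5 and 9.77 log2 CPM, against 9.31, 9.3 and 9.23 in the doxorubicin controls. At 1 nM treated libraries were at 9.22 to 9.3 under doxorubicin and 9.21 to 9.24 under epirubicin. They were at 9.09 to 9.19 and 9.1 to 9.42 at 5 nM, and 8.79 to 8.87 and 8.86 to 9.04 at 15 nM. Only at 10 and 50 nM did all doxorubicin libraries lie higher, and there the gap between the controls adds to the difference as well. At 1, 5 and 15 nM the treated ranges overlapped, so those calls lean on the controls most. The tables were normalized separately, so such levels are only a rough guide across them.

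Genes near ABCB1 moved both ways at 100 nM, given here in order of position with values in doxorubicin and epirubicin. Before ABCB1 lay ELAPOR2 at -0.19 and -0.28, DMTF1 at 0.56 and 0.90 and TMEM243 at 0.24 and 0.28. Next were CROT at 0.24 and 0.50 and ABCB4 at 1.49 and 2.85. Past the start of ABCB1 lay RUNDC3B at -0.98 and -0.39, SLC25A40 at -0.85 and -0.17 and DBF4 at -1.14 and -0.25. ADAM22 was at -0.92 and -0.47, SRI at -1.14 and -0.43 and STEAP4 at 1.90 and 0.15. ELAPOR2 under doxorubicin and RUNDC3B, SLC25A40 and STEAP4 under epirubicin did not pass the threshold.

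The change at 1 nM was shared, with 952 genes up and 822 down under both drugs. The control and 1 nM depth ranges overlapped in 2 of 2 drugs. With 3 libraries per group such ranges mostly overlap whatever the cause, so this decides nothing on the depth of the control libraries. Control cultures that differ from all treated cultures cannot be told apart from a response for genes called under epirubicin and read under doxorubicin. There the lowest median signed change of the 7 doses, 0.028 at 100 nM, was 0.14 of the highest, 0.204 at 15 nM (0.09 to 0.25 over libraries). Without 100 nM the ratio was 0.51, and control and 100 nM libraries could have been handled together. Same-numbered ones deviated together with a lowest correlation of 0.31 across genes, which is only a hint, since the pairs are not independent. For genes called under doxorubicin and read under epirubicin the ratio was 0.63 (0.58 to 0.74), so such controls may account for part of it there, as may a response that lasts through all doses. NR4A3 stood at 218, 153 and 280 CPM in the doxorubicin controls and at 230, 167 and 315 at 100 nM, against 5.6, 60.6 and 8.25 at 1 nM.

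Splits of the 6 libraries of a dose and its control into groups of 3 number 10, too few for a share under 0.05. Of these 1, the real one, gave the most genes at each dose. In order of rising dose, the real counts for doxorubicin were 2661, 3097, 5693, 9433, 9083, 9017 and 8934, and the highest others 0, 2, 1, 0, 0, 1 and 2. For epirubicin the real counts were 5947, 6402, 9106, 9298, 8290, 8481 and 8763, and the highest others 8, 1482, 0, 1, 7, 0 and 0.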
